A study of Mus musculus with 12 samples.

How the data were processed

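The series holds 12 whole-transcript microarrays of cultured mouse cardiac fibroblasts that had become myofibroblasts, in 4 groups of 3 (carrier, sCD74, MIF, and sCD74 with MIF). Per the labels' protocols, the cells were treated for 8 h with 40 nM sCD74, 8 nM MIF or both, and biotin-labelled cDNA was made from total RNA with the Affymetrix WT Plus kit. The submitters' processing notes name Affymetrix Expression Console, RMA and Transcriptome Analysis Console without versions. RMA in its usual form corrects background, normalizes arrays to the same distribution of probe intensities and summarizes the probes of a probe set, which can hide a global shift in RNA amount. Scanner files were not used here.

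The deposited values are on a log2 scale, 1 column per sample, and were used as deposited. They ran from 3.08 to 18.39, and 231 to 251 probe sets per array lay above 16, the log2 of the largest value a 16-bit scanner gives. A step beyond plain RMA that rescaled the values is not given in the sources used here, so differences are on the log2 scale of the deposited table and their size as a fold depends on that scale. Array medians lay between 8.01 and 8.14. The gap between the medians of positive and negative control probe sets, a measure of signal over background, ranged from 3.67 to 4.25.

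Of 28846 probe sets, 6640 were controls and were left out of all tests. Of the other 22206, 19572 had a single gene symbol in the platform's probe table, 0 had several and 2634 had none and were not named or tested. All 19572 were matched by Entrez ID to a table of RefSeq genes of the assembly GRCm38.p6, used for names only, and 0 symbols changed. Where probe sets shared a symbol, the one with the highest mean over the 12 arrays stood for the gene, which dropped 67 and left 19505 genes. Among these, 37 genes had values identical to those of another gene. The genome build of the probe sets is not given in the sources used here, so no coordinates are printed.

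Groups came from the sample labels. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) with 4 group means over all 12 arrays, which share an estimate of the spread. The test was two-sided for 6 contrasts, with Benjamini-Hochberg adjustment within each contrast at a threshold of 0.05. Errors given with the log2 differences of these contrasts are standard errors of that fit, and those given with levels are SDs over 3 arrays. The tests, the 17 gene lists and 8 cell type marker lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists were tested with limma's camera at a preset correlation between genes of 0.01, again with the correlation estimated, and with fry, adjusted over the 25 lists within each contrast. No list passed fry's directional test: its smallest adjusted p was 0.226, for NF-kappaB targets, chemokines and necroptosis genes with co-treatment against carrier. Where text speaks of a list call with no further words, the preset correlation was used, and none of these calls held with an estimated correlation. Of the list members, 3 of 29 in the extracellular matrix list also stood in the fibroblast list, Birc2 and Birc3 stood in the NF-kappaB and the necroptosis lists, and Zbp1 in the interferon and the necroptosis lists.

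The rule for named genes took up to 10 called genes in each direction per contrast whose 3 differences between same-numbered arrays had the sign of the change, the called members of each list with the 4 smallest p, 9 genes fixed in advance, of which 7 were measured, and, in a contrast without calls, the 3 genes with the smallest p in each direction, passing over unnamed predicted genes and olfactory receptor, microRNA, small nucleolar RNA and vomeronasal receptor families. The examples given for lists, with their values, are drawn from the members with the smallest p or were chosen after their values were seen. The same holds for genes called only in a fit with the replicate block. Where the mean of a named gene lay below 7.53, the mean of the negative control medians of the arrays, in a compared group, the text says so and gives no size for the difference, a rule added after the results were seen.

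The sample titles give all arrays of a replicate number a shared code, and the numbers were taken to pair the samples across groups. As a check, the deviations of same-numbered arrays from their group means correlated with r between 0.097 and 0.647 (median 0.433, above 0.1 in 17 of 18 pairs), against -0.544 to 0.175 (median -0.212) for arrays of different number from different groups, and 12 of 12 arrays correlated best with their own number. The fit with the replicate number as a block was run as an alternative for every result. The block lowered the median residual SD from 0.210 to 0.175. The blocked value is printed beside a result where it changed a call.

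Other alternatives were centring each array on its median, quantile normalization once more, all non-control probe sets, leaving out the dimmest 30% of genes, an intensity trend with robust variance, an ordinary unmoderated test, a fit of the compared arrays only, array weights, and leaving out each array in turn. Without a single array the compared groups hold different replicate numbers, in a fit without the block. A result lost there can reflect differences between these numbers. Added after the data were seen were the block together with trend and robust variance, the block together with an estimated correlation, leaving out the 4 arrays of replicate number 1, average effects of each protein over the presence of the other in the fit with the block, and, for the lists, the scaling alternatives and leaving out each array.

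The procedure was tested on simulated data with the real gene means and replicate-number effects and noise of the residual SD of the fit with the block, comparing co-treatment with carrier over 19505 genes of which 200 were changed. A log2 change of 0.5 was recovered in 0% of the changed genes with and without the block, a change of 1 in 57.5% without and 86% with the block, and a change of 2 in 97.5% and 100%. With the block, 9 unchanged genes were called at a change of 1 and 9 at a change of 2, against 0 and 2 without it. In camera with the preset correlation, a list shifted by 0.3 was called at adjusted p = 9.0e-10, and with no shift it had 0.953 while 1 other list was called. The simulated noise was independent between genes, so this run does not test the list calls where members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.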

Results

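Gene expression was measured on 12 microarrays, each carrying RNA of a culture of mouse cardiac fibroblasts. The cells came from newborn C57BL/6J hearts and were grown until they had become myofibroblasts, the contractile, matrix-secreting form of the fibroblast. They received carrier, 40 nM soluble CD74 (sCD74, the extracellular part of a receptor for MIF), 8 nM macrophage migration inhibitory factor (MIF, a cytokine), or both proteins together for 8 h, with 3 arrays in each of the 4 groups. The comparisons ask which transcripts differ after each protein alone and after both, what each adds to the other, and whether the response to both departs from the sum of the single responses. The median log2 value per array lay between 8.01 and 8.14, and arrays of a group correlated with r between 0.988 and 0.995 across probe sets. The number of arrays limits the precision: the median standard error of a difference between groups was 0.17 on the log2 scale. With the replicate number as a block it was 0.14. Errors printed with the 6 contrasts come from the fit without the block, which leaves differences between replicate numbers in them. The labels do not say whether the replicates of a group came from separate isolations, so p-values measure only the spread between these arrays.

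The cultures carried high levels of myofibroblast transcripts in every group. Acta2, which encodes smooth muscle alpha-actin and marks myofibroblasts, stood at a log2 value of 16.46 ± 0.10 (SD, n = 3) with carrier, 16.59 ± 0.34 with sCD74, 16.55 ± 0.20 with MIF and 16.64 ± 0.29 with both. Some macrophage transcripts were also abundant. The highest of the 14 measured markers were Lyz2 (lysozyme), Mrc1 (the mannose receptor) and Fcgr3 (an Fc receptor). Their means over the 12 arrays were 17.22, 16.52 and 15.88, while Cx3cr1 (8.16) and Cd14 (8.48) were the lowest. Arrays that share a replicate number resembled each other across treatments, and the first principal component, with 37.4% of the variance, set replicate number 1 apart from the others. In replicate number 1 all 14 measured macrophage markers passed limma's test as lower than in numbers 2 and 3, with a median log2 difference of -0.99. Of 11 endothelial markers, with a median of +1.19, 8 passed as higher and 1, Vwf, as lower (-0.40).

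Co-treatment with sCD74 and MIF gave the most genes with a difference of at least 2-fold from carrier, 23 against 8 for MIF alone and 2 for sCD74 alone. These counts were not tested, and the 2-fold limit depends on the scale of the deposited values. They include genes below the negative control median with carrier, such as Acod1 and Slc7a3 with co-treatment and Rsad2 with sCD74. Targets and feedback regulators of the transcription factor NF-kappaB lay above carrier in 24 of 26 measured members, with a median log2 difference of +0.42. Among them were Birc3, an inhibitor of apoptosis (+0.83 ± 0.23, SE), Nfkbia, which encodes the NF-kappaB inhibitor IkB-alpha (+0.63 ± 0.21), Sod2, the mitochondrial superoxide dismutase (+0.61 ± 0.20), and the adhesion molecule Vcam1 (+0.44 ± 0.15). Chemokines and cytokines were higher in 26 of 30 members, with a median of +0.33, including the monocyte attractants Ccl2 (+1.71 ± 0.51) and Ccl7 (+1.23 ± 0.31). All 28 interferon-stimulated genes lay above carrier, with a median of +0.54, as in Oasl2 (+1.42 ± 0.45) and the GTPase Gbp2 (+1.47 ± 0.64). Counts and medians of lists, here and below, keep members that lay below the negative control median of 7.53. With carrier and with co-treatment these were, among others, Oasl1, Oas1a, Cxcl11, Lif and Ptgs2.

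Each of these 3 lists rose against the other genes in limma's camera test with its preset correlation, at adjusted p = 6.7e-09 for NF-kappaB targets, 4.7e-08 for chemokines and 9.5e-10 for interferon-stimulated genes. The calls were lost with an estimated correlation between genes: adjusted p = 0.170 with an estimated correlation for NF-kappaB targets and for chemokines, and 0.592 for interferon-stimulated genes. In the pairs of replicates 1, 2 and 3, the mean of the list differed from carrier by +0.34, +0.20 and +0.63 for NF-kappaB targets, by +0.33, +0.38 and +0.64 for chemokines, and by +0.24, +1.04 and +0.61 for interferon-stimulated genes. An exact two-sided permutation test of the list means, which leaves the pairing by replicate number out of account, gave p = 0.1, the smallest that 3 against 3 allows, for NF-kappaB targets and chemokines, and p = 0.3 for interferon-stimulated genes, whose means also differed between replicate numbers. Without co-treated replicate 2 the median of the interferon list was +0.30 (adjusted p = 0.00495). Macrophage markers had a median of -0.15 in this comparison (adjusted p = 0.50, 0.0461 with the replicate number as a block, and 0.766 with block and estimated correlation).

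No single gene passed limma's test of co-treatment against carrier with Benjamini-Hochberg adjustment. The count was 0 of 19505 genes, against 780 with an unadjusted p under 0.05, fewer than 5% of the genes. The fit without the block leaves the differences between replicate numbers in its residual. With the replicate number as a block the count was also 0. There, 1606 genes had an unadjusted p under 0.05, more than the 975.25 that make up 5% of the genes. Adding an intensity trend and robust variance to that block, a setting chosen after the data were seen, called 6 genes, all higher with co-treatment: Acod1, which makes itaconate in activated macrophages, Clec4e, a lectin receptor of myeloid cells (+1.74 ± 0.55), Gbp2, the amino acid transporter Slc7a3, the anion transporter Slco3a1 (+0.99 ± 0.19) and Birc3. Their adjusted p in that fit lay between 0.0185 for Acod1 and 0.0246 for Gbp2, and was 0.999 without block, trend and robust variance. With carrier, Acod1 (5.72) and Slc7a3 (7.22) lay below the mean negative control median of 7.53, and Acod1 reached only 7.60 with both proteins, so the sizes of these differences are not given. Adjusted over the list alone, 1 member passed among chemokines, Ccl7 at adjusted p = 0.0453, and 1 in the TGF-beta response list, Ltbp2, a matrix protein (+0.85 ± 0.17, adjusted p = 0.00592). With the replicate block, 8 chemokines, 11 NF-kappaB targets and 15 interferon-stimulated genes passed adjusted over the list alone, all of them higher, as did Birc3 and Ripk3 in the necroptosis list, Ltbp2 and the metallothionein Mt2. The genes with the smallest p that did not pass over all genes were Slco3a1, Ltbp2 and the amino acid transporter Slc7a2 (+0.73 ± 0.15) on the higher side, and Sva, Akr1c12 and Ctsm, all below the negative control median in both groups, on the lower side.

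**Figure D1:**
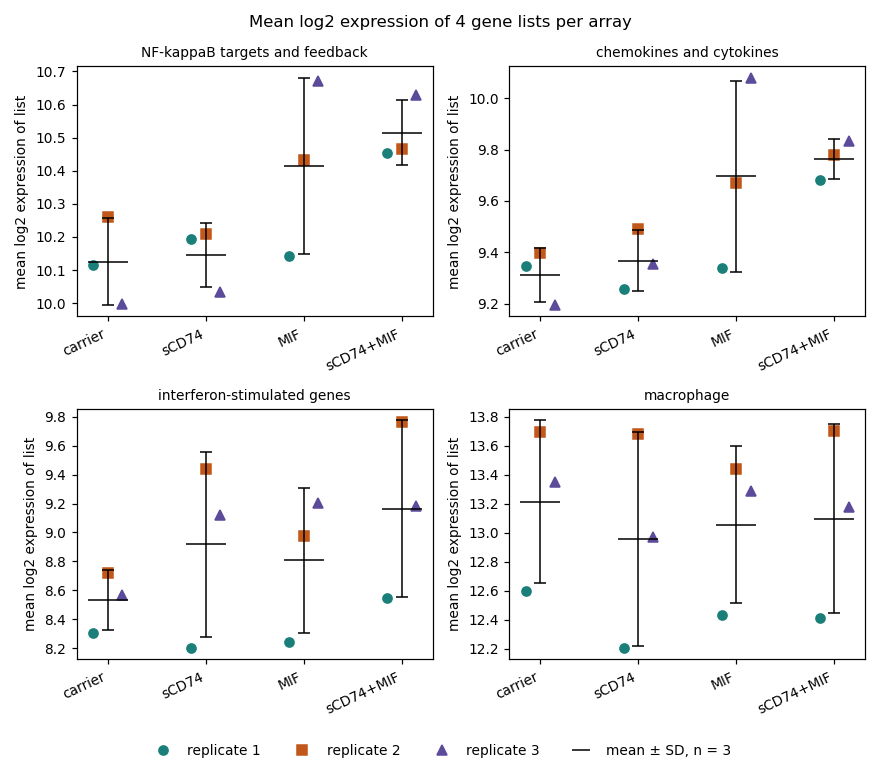
Mean log2 expression of 4 gene lists (vertical axis) on each of the 12 arrays, by treatment group (horizontal axis), with symbols for the replicate number, a bar for the group mean and whiskers of 1 SD (n = 3). The NF-kappaB list had a mean of 10.13 with carrier, 10.15 with sCD74, 10.42 with MIF and 10.52 with both proteins, and the macrophage list lay lowest in replicate number 1 of every group.

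Smaller differences with co-treatment were found in 4 further lists. Genes of necroptosis and death receptor signalling, a regulated form of cell death, were higher in 16 of 19 members with a median of +0.10, including Birc3 and Ripk3, the kinase that activates Mlkl (+0.50 ± 0.16). Cholesterol synthesis genes were higher in 14 of 14 members with a median of +0.27, including Sqle (+0.60 ± 0.25) and Insig1 (+0.35 ± 0.18). Genes of hypoxia and glycolysis had a median of +0.17 (17 of 20 higher, Ldha +0.27 ± 0.12) and those of the unfolded protein and amino acid response +0.13 (15 of 18 higher, Phgdh +0.49 ± 0.22). The preset camera test called these 4 lists at adjusted p = 7.5e-04, 2.6e-05, 0.0132 and 0.0188, in the order given. The adjusted p with an estimated correlation was 0.170, 0.592, 0.728 and 0.592. The last 3 of these lists rested on replicate number 1: without its 4 arrays, an alternative added after the data were seen, adjusted p was 0.678 for cholesterol synthesis and 0.831 for the other two. Without the co-treated array of replicate 1 alone it was 0.224 for cholesterol synthesis (median +0.13), 0.578 for hypoxia (median +0.06) and 0.339 for the unfolded protein list (median +0.07). The hypoxia and unfolded protein calls were also lost when quantile normalization was applied once more (0.0837 for both), the former without carrier replicate 3 (0.0530), the latter without carrier replicate 1 (0.255, median +0.05) or 2 (0.0747).

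The remaining lists did not pass in this comparison with the preset correlation. Their median log2 differences were -0.06 for MIF receptors and ligands, +0.01 for myofibroblast contractile genes, +0.05 for extracellular matrix, +0.08 for the TGF-beta response, +0.06 for matrix proteases and inhibitors, and +0.11 for antigen presentation. They were -0.02 for apoptosis and survival, +0.06 for the cell cycle, 0.00062 for immediate early genes and +0.04 for oxidative and metal stress. Among markers of other cell types, the medians were -0.06 for endothelial cells, +0.02 for cardiomyocytes, +0.05 for smooth muscle and pericytes, -0.03 for epicardial and mesothelial cells, -0.07 for lymphocytes, +0.04 for Schwann and glial cells and -0.07 for fibroblasts.

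Among the genes fixed in advance, Ripk3 stood at a log2 value of 8.47 ± 0.23 (SD, n = 3) with carrier, 8.72 ± 0.25 with sCD74, 8.96 ± 0.15 with MIF and 8.97 ± 0.09 with both. Mlkl, which encodes the pore-forming effector of necroptosis, stood at 11.99 ± 0.07, 12.08 ± 0.15, 12.32 ± 0.25 and 12.40 ± 0.31. Neither passed limma's test in any of the 6 contrasts. Casp8, the caspase that restrains necroptosis, lay between 15.52 and 15.64 in the 4 groups. Mif itself had means of 10.55, 10.78, 10.90 and 10.94, Cd44 of 12.76, 12.74, 12.89 and 12.86, and Cxcr4 of 10.65, 10.36, 10.61 and 10.30, in the order carrier, sCD74, MIF and both, with no call. Cd74 and Ripk1 were not analysed here.

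**Figure D2:**
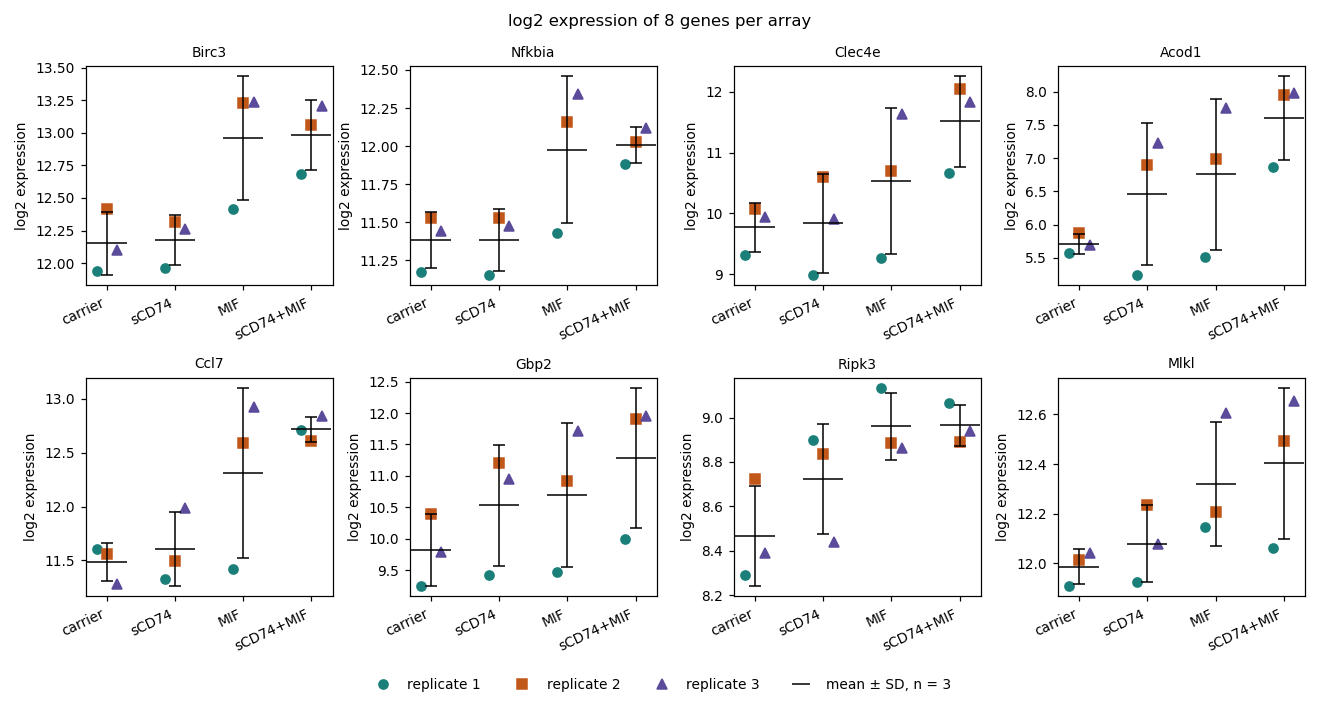
log2 expression of 8 genes (vertical axes) on each array by treatment group (horizontal axes), with symbols for the replicate number, a bar for the group mean and whiskers of 1 SD (n = 3). Birc3 averaged 12.15 with carrier and 12.18 with sCD74, against 12.96 with MIF and 12.98 with both, and the MIF array of replicate number 1 lay below the other MIF arrays in Birc3, Nfkbia, Clec4e, Acod1, Ccl7 and Gbp2. Acod1 lay near or below the negative controls in every group.

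MIF alone was compared with carrier to find the transcripts that respond to the cytokine without sCD74. NF-kappaB targets were higher in 22 of 26 members with a median of +0.29, with Birc3 at +0.81 ± 0.23, Nfkbia at +0.60 ± 0.21 and Vcam1 at +0.42 ± 0.15. Chemokines and cytokines were higher in 24 of 30 with a median of +0.26, including Ccl2 (+1.26 ± 0.51), Ccl7 (+0.83 ± 0.31) and Cx3cl1, a membrane-bound chemokine (+0.55 ± 0.19). TGF-beta response genes had a median of +0.14 (16 of 19 higher), including Ltbp2 (+0.55 ± 0.17) and Ccn2, a matricellular growth factor (+0.52 ± 0.25). Interferon-stimulated genes had a median of +0.23 (22 of 28 higher) and hypoxia and glycolysis genes of +0.15 (18 of 20 higher).

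In the preset camera test these lists rose at adjusted p = 4.7e-06 for NF-kappaB targets, 8.7e-06 for chemokines, 0.0132 for the TGF-beta response, 0.0429 for interferon-stimulated genes and 0.0176 for hypoxia and glycolysis. The adjusted p with an estimated correlation was 0.349 for the first 3, 0.819 for interferon-stimulated genes and 0.814 for hypoxia and glycolysis. The replicates differed in size: in replicates 1, 2 and 3 the list mean differed from carrier by +0.02, +0.17 and +0.67 for NF-kappaB targets and by -0.01, +0.27 and +0.89 for chemokines. Without MIF replicate 3 the adjusted p was 0.0540 for NF-kappaB targets (median +0.20), 0.0979 for chemokines (median +0.22), 0.935 for interferon-stimulated genes (median +0.09) and 0.0979 for hypoxia and glycolysis. The interferon call was also lost without carrier replicate 1 (0.399) or MIF replicate 2 (0.261), the TGF-beta call without carrier replicate 1 (0.0723, median +0.18) or 2 (0.114, median +0.13), and the hypoxia call without carrier replicate 3 (0.0754) or MIF replicate 1 (0.239, median +0.08). Without all 4 arrays of replicate number 1 the TGF-beta and hypoxia lists stood at 0.0745 and 0.136.

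With the replicate block, extracellular matrix, matrix protease, necroptosis and immediate early lists also passed as higher with MIF, at adjusted p = 0.0172, 0.0247, 0.0315 and 0.0411, and macrophage markers passed as lower, with a median of -0.19 at adjusted p = 0.00151. With block and estimated correlation together the adjusted p was 0.440 for the matrix protease and necroptosis lists and 0.565 for the other 3. No gene passed limma's test of MIF against carrier: 0 genes without and 0 with the block, with 653 and 1254 at an unadjusted p under 0.05. The fit with block, trend and robust variance called Birc3 alone, at adjusted p = 0.0462, against 0.690 with the block only. The smallest p on the higher side belonged to Slco3a1 (+0.85 ± 0.19), Slc7a2 (+0.66 ± 0.15) and Ddx43, and on the lower side to Abcc6 (-0.58 ± 0.14), Bcl7c and Ctsm, none of which passed. Ddx43, Bcl7c and Ctsm lay below the negative control median in both groups. Adjusted over the list alone 0 members passed, and with the block 6 chemokines, 7 NF-kappaB targets and 2 necroptosis genes, Birc3 and Ripk3.

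sCD74 alone was compared with carrier to find the transcripts that respond to the soluble receptor. Interferon-stimulated genes were higher in 25 of 28 members with a median of +0.39, including the antiviral gene Rsad2 (below the negative control median with carrier), Cmpk2 (+0.62 ± 0.32) and Ifit2 (+0.50 ± 0.26). Extracellular matrix genes had a median of +0.12 (24 of 29 higher), with the collagen chains Col5a2 at +0.29 ± 0.12 and Col1a1 at +0.25 ± 0.14. Hypoxia and glycolysis genes had a median of +0.13 (17 of 20 higher). Macrophage markers lay below carrier in 12 of 14 members with a median of -0.28, as in Aif1 (-0.69 ± 0.71) and Fcgr3 (-0.37 ± 0.26). NF-kappaB targets and chemokines had medians of +0.07 and +0.05.

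The preset camera test called interferon-stimulated genes (adjusted p = 8.0e-06), extracellular matrix (0.0190) and hypoxia and glycolysis (0.0424), and all 3 stood at adjusted p = 0.974 with an estimated correlation. The interferon list mean differed from carrier by -0.10, +0.71 and +0.55 in replicates 1, 2 and 3, and without sCD74 replicate 2 its adjusted p was 0.333 and its median +0.14. The matrix call was lost without any of carrier replicate 1 (0.0551) or 2 (0.570, median +0.02) and sCD74 replicate 1 (0.339, median +0.03) or 3 (0.0957). The hypoxia call was lost without any of carrier replicate 1 (0.0859), 2 (0.117) or 3 (0.179, median +0.06) and sCD74 replicate 1 (0.767), where its median turned to -0.02. Both were lost with quantile normalization once more (0.0682 and 0.134) and without replicate number 1 (0.338 and 0.952). The macrophage list had an adjusted p of 0.0636 without the replicate block and passed with it at 2.7e-07 (0.649 with block and estimated correlation). Its mean differed by -0.39, -0.01 and -0.37 in replicates 1, 2 and 3, and with the block Aif1 and Tyrobp passed adjusted over the list alone. No gene passed limma's test of sCD74 against carrier in the fits without the block, with the block, or with block, trend and robust variance (0 in each), with 350 and 817 genes at an unadjusted p under 0.05 in the first and second. The smallest p belonged to Shmt1, Slc7a2 (+0.54 ± 0.15) and Oxtr on the higher side and to Bpifa5, Serpinb9e and Mfap2 (-0.73 ± 0.20) on the lower side, where those without a value lay below the negative control median in both groups.

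Adding MIF to sCD74, tested as co-treatment against sCD74 alone, gave a pattern in the NF-kappaB and chemokine lists like that of MIF against carrier. All 26 NF-kappaB targets were higher, with a median of +0.30, including Birc3 (+0.80 ± 0.23), Nfkbia (+0.62 ± 0.21) and Sod2 (+0.54 ± 0.20). Chemokines were higher in 27 of 30 with a median of +0.33, including Ccl2 (+1.39 ± 0.51), Ccl7 (+1.11 ± 0.31) and Ccl9 (+0.44 ± 0.17). Necroptosis genes had a median of +0.15 (13 of 19 higher, Tlr3 +0.38 ± 0.14), cholesterol synthesis genes of +0.20 (14 of 14) and interferon-stimulated genes of +0.26 (22 of 28).

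The preset camera test called these 5 lists at adjusted p = 1.0e-09, 1.7e-07, 0.00873, 0.00142 and 0.0289, in the order given. With an estimated correlation the adjusted p was 0.214 for NF-kappaB targets and chemokines, 0.279 for necroptosis, 0.919 for cholesterol synthesis and 0.998 for interferon-stimulated genes. The list means differed by +0.26, +0.26 and +0.60 for NF-kappaB targets and by +0.43, +0.29 and +0.48 for chemokines in replicates 1, 2 and 3, with an exact two-sided permutation p, again without the pairing, of 0.1 for each, the smallest possible. The median of the interferon list turned to -0.13 without sCD74 replicate 1 (adjusted p = 0.124) and to -0.09 without co-treated replicate 2 (0.375). Each of these runs left the groups with different replicate numbers, in a fit without the block. Within the pairs of replicates 1, 2 and 3 the list mean was higher with co-treatment each time. It stood at 8.55, 9.77 and 9.18, against 8.20, 9.44 and 9.12 with sCD74. The necroptosis call was lost without sCD74 replicate 1 (0.107) or co-treated replicate 2 (0.0916), and the cholesterol call without sCD74 replicate 3 (0.278, median +0.08), co-treated replicate 1 (0.599, median +0.07) or all of replicate number 1 (0.593). The macrophage list (median +0.15) and antigen presentation (+0.10) passed as higher with the replicate block at adjusted p = 0.0131 and 0.0158, and stood at 0.799 and 0.370 with block and estimated correlation. The block also brought 7 NF-kappaB targets, 3 chemokines and 1 necroptosis gene, Birc3, past the threshold adjusted over the list alone, where 0 passed without it.

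No gene passed limma's test of co-treatment against sCD74, 0 without and 0 with the block, with 520 and 1053 genes at an unadjusted p under 0.05. The fit with block, trend and robust variance called Clec4e (+1.68 ± 0.55) and Birc3, both at adjusted p = 0.0373, against 0.503 with the block only. The smallest p belonged to Akap3, Cacnb1 (+0.64 ± 0.15) and the chemokine Cxcl13 (+0.99 ± 0.23) on the higher side and to Psapl1, the interleukin 7 receptor Il7r (-0.51 ± 0.13) and Dtx3 (-0.51 ± 0.13) on the lower side. Akap3 and Psapl1 lay below the negative control median in both groups.

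Adding sCD74 to MIF, tested as co-treatment against MIF alone, gave calls in 3 lists. Interferon-stimulated genes were higher in 26 of 28 with a median of +0.27, as in Oasl2 (+0.71 ± 0.45). Cholesterol synthesis genes were higher in 14 of 14 with a median of +0.19 and cell cycle genes in 25 of 29 with a median of +0.11, as in Ccnb2 (+0.26 ± 0.15). NF-kappaB targets and chemokines had medians of +0.03 and +0.08 and did not pass (adjusted p = 0.346 and 0.411). Adjusted over the list alone, Oas1a passed in the fit with the replicate block, though it lay below the negative control median in both groups.

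The preset camera test gave adjusted p = 2.5e-05 for interferon-stimulated genes, 7.4e-04 for cholesterol synthesis and 0.0132 for the cell cycle, and 0.972 for all 3 with an estimated correlation. The interferon list mean differed by +0.30, +0.79 and -0.02 in replicates 1, 2 and 3, and its call was lost without MIF replicate 1 (adjusted p = 0.392, median +0.04) or co-treated replicate 2 (0.582, median +0.03). Macrophage markers had a median of +0.05 here (adjusted p = 0.894) and means of -0.03, +0.26 and -0.11 in these replicates. The cholesterol call was lost without MIF replicate 2 (0.315, median +0.07), co-treated replicate 1 (0.491, median +0.04) or replicate number 1 (0.0631). The cell cycle call was lost without MIF replicate 1 (0.145, median +0.06) or 2 (0.675, median +0.02) and co-treated replicate 1 (0.0696, median +0.06) or 3 (0.774, median -0.0080), without replicate number 1 (0.475) or with quantile normalization once more (0.0857). No gene passed limma's test, 0 without the block, with it, and with block, trend and robust variance, with 465 genes at an unadjusted p under 0.05 and 864 with the block. The smallest p belonged to Mdm1, Ipo4 (+0.49 ± 0.12) and Cdkl2 on the higher side and to Otop3, Kcnk7 and Cdsn on the lower side, where all but Ipo4 lay below the negative control median in at least 1 group.

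The interaction asks whether MIF had another effect in the presence of sCD74 than in its absence, on the log2 scale. Extracellular matrix genes had a negative interaction in 26 of 29 members with a median of -0.12, including Thbs1 (-0.42 ± 0.24), Col5a2 (-0.35 ± 0.17) and Col1a1 (-0.26 ± 0.20). The list fell in the preset camera test at adjusted p = 0.0392, and stood at adjusted p = 0.991 with an estimated correlation. NF-kappaB targets and chemokines had median interactions of -0.0044 and +0.07, with adjusted p = 0.898 and 0.905, so the test found no difference between the effects of MIF on these lists with and without sCD74. With the replicate block the macrophage list (median +0.28, 13 of 14 positive, adjusted p = 1.2e-05) and the TGF-beta response (median -0.21, 15 of 19 negative, adjusted p = 0.0181) passed too, and both stood at 0.676 with block and estimated correlation.

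The matrix call of the interaction was lost without replicate number 1 (0.259), with quantile normalization once more (0.0687), and without any of carrier replicate 1 (0.0827) or 2 (0.456, median -0.07), sCD74 replicate 1 (0.258, median -0.08) or 3 (0.0776), MIF replicate 1 (0.117) or 3 (0.0519) and co-treated replicate 2 (0.0562) or 3 (0.122). No gene passed limma's test of the interaction, 0 without the block, with it, and with block, trend and robust variance, with 363 genes at an unadjusted p under 0.05 and 752 with the block. The smallest p belonged to Obox2, Serpini2 and Tas2r129 on the positive side and to Shmt1, Kcnk7 and Cabcoco1 on the negative side. Kcnk7 lay below the negative control median in 2 groups and above it in the other two, and the other 5 genes lay below it in all 4.

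The 3 comparisons with carrier share their control arrays, which alone makes their log2 differences correlate across genes. The correlation was 0.526 between sCD74 and MIF, 0.551 between sCD74 and co-treatment and 0.631 between MIF and co-treatment, against 0.50, 0.50 and 0.499 in 100 simulations of unchanged groups. The covariance exceeded the simulated one by 0.00361, 0.00547 and 0.0106, in the order given. These values run across 19505 genes, which are not independent replicates. The 3 carrier arrays are too few to split into sets of 2 or more each, so part of the excess may come from the shared controls.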

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

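Of the tests in this part, the comparison of the effects of MIF with and without sCD74 was planned, while its repeat without replicate number 1, the split counts at an unadjusted p and the tests of explanations were chosen after the results were seen.

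Extracellular matrix genes differed in their response to MIF between cultures with and without sCD74 by the interaction test of the list (adjusted p = 0.0392, median -0.12, mean interaction below 0 in 3 of 3 replicates). With the replicate block, the TGF-beta response list (adjusted p = 0.0181, median -0.21) and the macrophage list (adjusted p = 1.2e-05, median +0.28) also differed. The adjusted p was 0.991 for extracellular matrix with an estimated correlation and 0.676 for the other two with block and estimated correlation. The first call was lost without replicate number 1 (adjusted p = 0.259).

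The NF-kappaB and chemokine lists were higher in MIF-treated cultures with the preset correlation, at adjusted p = 0.349 with an estimated correlation for MIF and 0.170 for co-treatment against carrier and 0.214 for co-treatment against sCD74, while without sCD74 their means in replicate 1 differed by only +0.02 and -0.01 and both calls were lost without MIF replicate 3 (0.0540 and 0.0979). More macrophage RNA would raise macrophage markers, if treatment left their level per macrophage unchanged, which was not tested. Under that assumption, more macrophage RNA with MIF than with carrier is argued against. The median of the markers was -0.19 (95% bootstrap interval over markers from -0.23 to -0.11, mean below 0 in 3 of 3 replicates). With co-treatment against carrier their median was -0.15 (from -0.24 to -0.09), with means of -0.19, +0.0079 and -0.17 in replicates 1, 2 and 3. Under the same assumption, these values argue against a rise in macrophage RNA as large as the NF-kappaB median of +0.42. A small rise in replicate 2 stays open. With co-treatment against sCD74 the explanation stays open (median +0.15, from 0.04 to 0.20, above 0 in 3 of 3 replicates, though below the NF-kappaB median of +0.30). Intervals over markers, here and below, do not measure the spread between cultures. Random lists matched on mean expression, here and below, bear on scaling and not on chance. The lists and replicates set against them were picked after their values were seen. Level-dependent scaling of the arrays would move genes of like expression alike, but the NF-kappaB medians of +0.29, +0.42 and +0.30 in these comparisons lay above 0.085, 0.10 and 0.082, the upper ends of the central 95% of 10000 random lists matched on mean expression. An effect of MIF treatment predicts a difference beyond exchanges of arrays within replicate numbers, and the exact two-sided permutation p over all such exchanges was 0.0185 for the NF-kappaB list mean (0.154 adjusted over 25 lists, higher in 3 of 3 replicates). The hypothesis that MIF raised these transcripts, in fibroblasts or in the macrophages of the cultures, may hold and was found and tested on the same data, while a contaminant carried with the added MIF was not tested.

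The interferon-stimulated list was higher in sCD74-treated cultures of replicates 2 and 3 but not of replicate 1 when sCD74 was compared with carrier. The macrophage markers had a mean difference of -0.012 in replicate 2 (95% bootstrap interval over markers from -0.09 to +0.06) and of -0.37 in replicate 3 (from -0.49 to -0.26). These values argue against a rise in macrophage RNA as large as that of the interferon list, while a small rise in replicate 2 stays open. This reading assumes that sCD74 left marker levels per macrophage unchanged, which was not tested. Level-dependent scaling is argued against. The list median of +0.53 in these replicates, picked because the list was high in them, lay above 0.063. That value was the upper end of the central 95% of matched random lists. An effect of sCD74 treatment was not decided: the exact two-sided permutation p over all exchanges of arrays within replicate numbers was 0.0833 (0.787 adjusted over 25 lists, higher in 3 of 3 replicates once cultures with MIF were included), and a p that misses the threshold excludes nothing.

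Replicate number 1 stood apart from numbers 2 and 3, with 3204 genes called between them in limma's fit with the block (1372 higher, 1832 lower). A lower share of the main cell type alone would raise the markers of all other types, but macrophage markers had a median of -0.99 (95% bootstrap interval from -1.31 to -0.71) and endothelial markers of +1.19 (from 0.39 to 2.33). Level-dependent scaling is argued against by the endothelial median, which lay above 0.15, the upper end of the central 95% of matched random lists. Lower array quality would narrow the gap between control medians in replicate 1, which was the narrowest of its group in 2 of 4 groups. In the MIF group it was narrowest by little, 4.04 against 4.06 in replicate 2. A loss of signal would also not raise endothelial markers above genes of like expression. The marker values argue against lower quality as the only source of the marker differences, while a contribution stays open. A change of several cell types at once stays open, and beyond the share of the main cell type no biological explanation was tested, since the design names none.

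For each of the 5 comparisons of groups of 3, all 10 splits of the 6 arrays gave at least the 0 genes of the real split, and the highest count of the others was 0. A real count of 0 fixes this outcome, and with 10 splits the share could not fall under 0.05 in any case. At an unadjusted p under 0.05, the real split of co-treatment and carrier gave 780 genes, the 3 other splits that part the same-numbered arrays gave 439 to 783, and the splits that keep some of them together 620 to 2154. In the other comparisons the real split also lay within the range of the 3 splits that part these arrays: 350 against 322 to 450 for sCD74 and 653 against 394 to 743 for MIF, each with carrier, and for co-treatment 520 against 295 to 525 with sCD74 and 465 against 362 to 912 with MIF. For the interaction, 100 of 100 assignments of the 12 arrays, the real one included, gave at least its 0 genes. The real count of 0 fixes this outcome as well, so the share decides nothing on chance. The highest other assignment gave 652 genes, which points to a structure of the samples.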

How the results depend on the processing

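The alternatives that paired the block with trend and robust variance or with an estimated correlation, the runs without replicate number 1, and the list tests under other scalings or without single arrays were chosen after the results were seen. The replicate block alone changed none of the gene counts, which stayed at 0 in all 6 contrasts, and beyond the list calls given beside the results it changed no other call. No gene was called under any alternative fixed in advance. The block with trend and robust variance called 1 gene for MIF against carrier, 6 for co-treatment against carrier and 2 for co-treatment against sCD74, and the cause was not tested. Leaving out each array in turn gave 0 genes in every contrast. Of 1511 alternative values of 86 named genes and contrasts, 9 were called, all in that fit, and 70 had the other sign.

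With an estimated correlation, the adjusted p of the NF-kappaB and chemokine lists was 0.349 for MIF and 0.170 for co-treatment against carrier and 0.214 for co-treatment against sCD74. That of the interferon list was 0.974 for sCD74, 0.819 for MIF and 0.592 for co-treatment against carrier, 0.998 against sCD74 and 0.972 against MIF. With the replicate block and an estimated correlation, NF-kappaB and chemokines stood at 0.440 each for MIF, at 0.304 and 0.285 for co-treatment against carrier and at 0.310 each against sCD74, and the interferon list at 0.649, 0.601, 0.285, 0.799 and 0.756. Within each fit, these runs differed from the preset ones only in the correlation between genes, preset at 0.01. Without the block it was estimated at 0.192 for NF-kappaB targets, 0.125 for chemokines and 0.697 for interferon-stimulated genes. With the block the estimates were 0.378, 0.227 and 0.467. All lay above the preset, so the preset p-values assume less shared variation among list members than was estimated here. The source of that shared variation was not tested.

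Without single arrays, the adjusted p ranged from 4.6e-14 to 0.0979 for chemokines and from 3.3e-16 to 0.0540 for NF-kappaB targets with MIF, from 4.4e-08 to 7.2e-05 and from 5.4e-09 to 1.7e-05 with co-treatment against carrier, and from 9.6e-07 to 2.1e-04 and from 4.5e-09 to 2.2e-06 against sCD74. For the interferon list it ranged from 3.5e-20 to 0.333 for sCD74, 2.0e-08 to 0.935 for MIF, 6.8e-19 to 0.00495 for co-treatment against carrier, 2.5e-08 to 0.375 against sCD74 and 3.7e-14 to 0.582 against MIF. Against sCD74 its median turned negative without sCD74 replicate 1 (adjusted p = 0.124) or co-treated replicate 2 (0.375). These runs broke the pairing, and within the pair of each replicate number the list mean was higher with co-treatment. Signal over background, a gap of 3.67 to 4.25 between control medians, limits what can be said of dim genes.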

Other observations

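The average effects of each protein over the presence and absence of the other, in the fit with the replicate block, were chosen after the results were seen, as were the tests over replicate numbers.

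Averaged over cultures with and without sCD74, 1 gene was called for MIF, and none of the 25 lists passed the exact test after adjustment. Birc3 passed limma's test at adjusted p = 0.0486 (+0.81 ± 0.10, SE, higher in 3 of 3 replicates), and no other gene passed with the block alone, while 1591 had an unadjusted p under 0.05. With trend and robust variance added, 3 genes passed: Birc3, Nfkbia (+0.61 ± 0.10) and Clec4e (+1.22 ± 0.20), the last 2 at adjusted p = 0.0179. Without the block 0 genes passed. The cytokine gene Tnf, at the negative control median with carrier, Ccl7 (+0.97 ± 0.19) and Acod1, mostly below it, were next by p and did not pass. Genes of necroptosis and death receptors had a mean difference of +0.12, +0.09 and +0.20 in replicates 1, 2 and 3, with an exact two-sided permutation p of 0.00926, the smallest that the exchanges of arrays within replicate numbers can give, and 0.154 adjusted over 25 lists. For the average effect of sCD74, 0 genes passed with the block, 0 with trend and robust variance added and 0 without the block, with 944 genes at an unadjusted p under 0.05 with the block. Slc7a3, below the negative control median with carrier, had the smallest p (adjusted p = 0.992).

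Between replicate numbers 3 and 2, limma called 224 genes, 86 higher and 138 lower in number 3, in the fit with group and number. Of 15 cardiomyocyte markers 11 passed as lower in number 3, with a median of -0.96, including the myosin light chain Myl2 (-3.08 ± 0.15) and the myosin heavy chain Myh6 (-2.97 ± 0.14). Another was Pln, a regulator of the calcium pump, which lay below the mean negative control median in number 3. Of 11 endothelial markers 5 passed as higher, among them Cdh5 (+1.33 ± 0.17). In replicate number 1 against 2 and 3, the endothelial genes Cdh5 (+2.67 ± 0.15), Pecam1 (+2.48 ± 0.16) and Kdr (+2.19 ± 0.13) were higher, and the macrophage genes Aif1 (-1.84 ± 0.11) and Csf1r (-1.64 ± 0.11) were lower. Of 28 interferon-stimulated genes 22 passed as lower in number 1, with a median of -0.71, and Ifit3 differed by -2.14 ± 0.18.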
